A study of Bruguiera gymnorhiza with 19 samples.

How the data were processed

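Cy5-labelled cRNA from 1 µg of leaf total RNA per sample was hybridised to 1-colour arrays, per the labels' protocols: 18 samples in 6 groups of 3 and 1 repeat array of the NaCl 0 h C RNA, 19 arrays in all. The deposited scanner files give, per the file headers, the foreground mean and median intensity of each spot on a linear scale, with no local background column; the scanner software is not given in the sources used here. Intensities ran from 0 to a ceiling of 65535. Each array held 12544 spots: 11997 mangrove probes of 35 to 40 nucleotides (11936 distinct sequences, 118 probes sharing a sequence with another), 70 negative controls, 151 empty spots and 326 spots named as quality controls. The median probe intensity per array ran from 52.9 to 1729, and 4 to 43 probes per array were saturated. On 4 arrays (NaCl 6 h C, sorbitol 0 h C, sorbitol 6 h C and sorbitol 24 h C) 2126 to 3216 probes had an intensity of 0, against 0 to 82 on the other arrays; these are called the arrays of lowest signal or the floor arrays. Of the 4, 3 belong to the sorbitol series, and all have the letter C.

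The authors' deposited table of intensity values was compared with the scanner files. In 16 of its columns the values form 1 set, which equals the mean of the sorted foreground medians of 18 arrays plus 16 (median gap 0.00133, highest gap 160, at the top of the scale), so these columns are quantile-normalized on a linear scale. Columns sorbitol 24 h B and C and the repeat array hold the foreground medians as scanned, so 3 columns lie on another scale; the column medians were 521 for the 16, 782 for sorbitol 24 h B, 83 for sorbitol 24 h C and 330.5 for the repeat array. The table is therefore used only as an alternative.

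Foreground means were background-corrected with normexp (offset 50) on all spots, log2 transformed and quantile-normalized between arrays over the mangrove probes. The normexp fit failed on the 4 floor arrays, where it returned values above those measured, and the foreground as given plus 50 was used there. This handling was chosen after the data and the counts of the failed run had been seen. The fit without any background correction, decided on earlier, bears on it. Spots excluded in the files (0 to 11 probes per array) were left out. A probe was detected on an array if its foreground mean exceeded the 95th percentile of the negative controls of that array, and 8655 probes (1031 from contigs, 7624 from single clones) detected in at least 3 of the 18 samples were kept. Both arrays of NaCl 0 h C were averaged first.

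All 18 samples entered 1 linear model with the 6 group means (limma, lmFit and eBayes, 12 residual degrees of freedom), with 9 comparisons and Benjamini-Hochberg adjustment within each; a probe was called at an adjusted p under 0.05. A difference of responses is the NaCl change from NaCl 0 h minus the sorbitol change from sorbitol 0 h. The text names the 2 highest and the 2 lowest log2 fold changes among called probes whose samples do not overlap, since the files give no gene descriptions; 1 probe that this rule picks is not reported here. The planned gene lists and their set tests need descriptions and were not run. Where a probe was above the negative controls on no array of the dimmer group, the fold is a bound, written "at least": the mean of the brighter group against the mean of, per array, the higher of the probe's own value and the lowest value among detected probes. Chance correlation between comparisons was taken from 20 simulations of unchanged groups with the fitted spread of each probe, and other splits of the samples were counted (10 for 3 against 3, 100 drawn for the differences of responses).

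The model was tested on simulated data of 8655 probes. For NaCl 6 h against NaCl 0 h it recovered 15, 38, 49 and 50 of 50 probes changed by 1, 1.5, 2 and 3 on the log2 scale and called 4 unchanged probes. For the difference of responses at 6 h it recovered 1, 15, 37 and 49 of 50 and called 6 unchanged probes. The simulated noise was drawn independently for each probe and sample, without floor arrays. These values therefore check the model and do not measure its error rate in the real data.

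The comparisons, the rule for naming probes and these other settings were chosen before the data were examined: no background correction, normexp with offset 0, median scaling, the authors' deposited table, no filter on dim probes, detection in all 18 samples, a trended and robust eBayes, the replicate letter as a block, only the first array of NaCl 0 h C, both 0 h groups pooled and each of the 18 samples left out. Added after seeing the data were the 0 h group of the other series as the control, the fit without the floor arrays, the floor arrays as a block and the authors' normalization rebuilt for the 18 arrays. No untreated leaves from 6 h or 24 h were among the samples. The analysis used R 4.3.3, limma 3.58.1 and jsonlite 2.0.0, and the figures Python 3.11.15 and matplotlib 3.10.9.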

Results

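Leaf transcript levels of Burma mangrove (*Bruguiera gymnorhiza*), a salt-tolerant tree of tropical coasts, were measured on 1-colour oligonucleotide arrays before and during treatment with NaCl or sorbitol. NaCl imposes ionic and osmotic stress together, whereas sorbitol, an uncharged sugar alcohol, imposes osmotic stress without the salt ions. The plants were 3 years and 7 months old, and their culture water was replaced by 500 mM NaCl or 1 M sorbitol. Leaves were taken at 0 h (untreated), 6 h and 24 h in both series, which gave 6 groups of 3 samples named A, B and C, and 1 RNA (NaCl 0 h C) was hybridised to a repeat array. Between 6382 and 8236 mangrove probes per sample (median 7090) lay above the negative control spots, and 8655 were tested. The highest number, 8236, was on sorbitol 6 h C, the array of lowest median intensity. Its detection threshold was also the lowest (2.51, against a median of 371 over the arrays), so detection was most lenient there. The files pair the probes with clone or contig identifiers and with sequences, not with gene names, so the probes are named here by identifier. Replicates were not stated to be separate plants, so the p-values measure the spread between these samples. The number of arrays, 3 samples per group, limits the precision of every value.

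**Figure D1:**
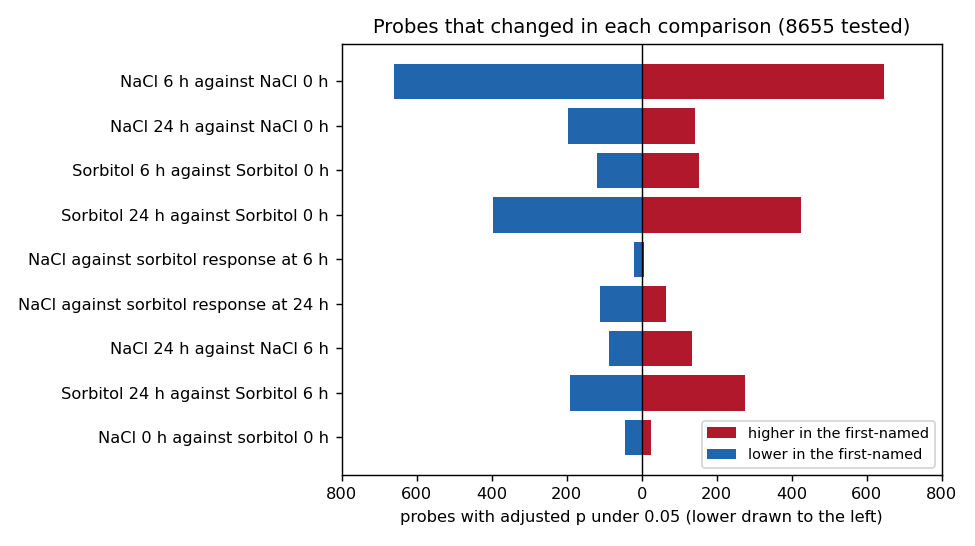
Number of probes past an adjusted p of 0.05 (limma) in each of the 9 comparisons; bars to the right count probes higher in the first-named group or response, bars to the left count probes lower in it. NaCl 6 h has the longest bars (647 higher and 659 lower), followed by sorbitol 24 h (425 higher and 397 lower). The order was the reverse with both 0 h groups pooled, the other series' 0 h group, median scaling or the authors' deposited table. It was also the reverse with NaCl 0 h A, NaCl 0 h B, NaCl 6 h A or NaCl 6 h B left out. The other fits kept it.

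After 6 h in NaCl, probe CL177Contig1_346_381 (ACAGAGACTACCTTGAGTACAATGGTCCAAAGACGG) rose from a log2 intensity of 10.36 ± 0.66 (SD, n = 3) to 15.42 ± 0.14, a log2 fold change of 5.06 (SE 0.35, limma adjusted p = 1.17e-08). On 1 of the 3 arrays at 6 h this spot was at the scanner ceiling, so the size is not exact. Probe Bg05-07_H14_769_803 (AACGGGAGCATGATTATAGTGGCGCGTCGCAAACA) was not above the negative controls in any NaCl 0 h sample (6.62 ± 0.50) and reached 11.12 ± 1.95 at 6 h, at least 8.11-fold higher (limma adjusted p = 0.000589). Probe Bg01-08_I17_100_134 (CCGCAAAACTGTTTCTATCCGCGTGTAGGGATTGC) fell from 12.28 ± 0.37 to 8.69 ± 0.55, a log2 fold change of -3.59 (SE 0.31, limma adjusted p = 4.23e-07). Probe CL991Contig1_77_111 (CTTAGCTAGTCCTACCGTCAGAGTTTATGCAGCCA) fell from 12.59 ± 0.17 to 9.19 ± 1.42, a log2 fold change of -3.41 (SE 0.53, limma adjusted p = 0.000597). In total 647 probes rose and 659 fell, 1306 of 8655. Of these, 819 changed at least 2-fold. The count was 331 without NaCl 0 h B, 724 without NaCl 0 h A, 2029 without NaCl 0 h C, 530 without NaCl 6 h A and 835 without NaCl 6 h B. With sorbitol 0 h as the control 217 probes changed, 150 of them called the same way against NaCl 0 h. The count was 683 with both 0 h groups pooled, 844 without the 4 arrays of lowest signal, 308 with median scaling (which moved the median of all probes to 0.11) and 8 with the authors' deposited table, in which CL177Contig1_346_381, Bg05-07_H14_769_803 and CL991Contig1_77_111 were not called.

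After 24 h in NaCl, probe Bg02-08_L08_505_539 (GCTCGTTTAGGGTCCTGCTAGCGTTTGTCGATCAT) rose from 9.03 ± 0.39 to 12.82 ± 0.15 (SD, n = 3), a log2 fold change of 3.79 (SE 0.59, limma adjusted p = 0.00124). Probe Bg05-15_J02_161_195 (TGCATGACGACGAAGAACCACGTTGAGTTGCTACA) was not above the negative controls at 0 h (7.85 ± 0.76) and reached 10.87 ± 0.34, at least 6.82-fold higher (limma adjusted p = 0.000267). Probe Bg04-20_E09_129_163 (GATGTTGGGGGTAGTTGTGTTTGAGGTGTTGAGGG) fell from 11.30 ± 0.65 to 8.85 ± 0.42, a log2 fold change of -2.45 (SE 0.36, limma adjusted p = 0.000919). Probe Bg05-22_G23_137_171 (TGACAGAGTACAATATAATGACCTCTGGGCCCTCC), above the negative controls in 2 of 3 samples at 0 h (9.28 ± 1.83) and in none at 24 h (6.70 ± 0.56), was at least 2.00-fold lower (limma adjusted p = 0.0200). That call was lost with sorbitol 0 h or both 0 h groups as the control, with the authors' normalization rebuilt, and without NaCl 0 h B, NaCl 24 h B or NaCl 24 h C. In all, 142 probes rose and 197 fell, 339 in total, of which 41.9% were higher. With median scaling 34 changed, 58.8% of them higher. The count was 36 without NaCl 0 h B, 210 without NaCl 0 h A, 555 without NaCl 0 h C, 93 without NaCl 24 h A, 53 without NaCl 24 h B and 177 without NaCl 24 h C. It was 85 with sorbitol 0 h as the control (42 called the same way in both), 121 with both 0 h groups pooled and 184 without the filter on dim probes. With the authors' deposited table it was 0, so none of the 4 named probes was called there. With the authors' normalization rebuilt it was 386.

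After 6 h in sorbitol, CL177Contig1_346_381 rose from 9.97 ± 0.77 to 14.86 ± 0.16 (SD, n = 3), a log2 fold change of 4.90 (SE 0.35, limma adjusted p = 1.06e-08). Probe CL1079Contig1_440_479 (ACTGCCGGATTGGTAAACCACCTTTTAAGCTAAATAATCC) was not above the negative controls at 0 h (6.97 ± 0.17) and reached 11.15 ± 0.51, at least 7.05-fold higher (limma adjusted p = 3.85e-07). Bg01-08_I17_100_134 fell from 12.84 ± 0.43 to 8.34 ± 0.38, a log2 fold change of -4.50 (SE 0.31, limma adjusted p = 1.06e-08). Bg02-09_D21_98_132 (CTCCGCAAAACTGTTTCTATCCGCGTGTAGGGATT), which shares 33 consecutive bases with Bg01-08_I17_100_134, fell from 13.01 ± 0.28 to 8.65 ± 0.22, a log2 fold change of -4.37 (SE 0.28, limma adjusted p = 2.64e-09). In total 152 probes rose and 119 fell, 271 of 8655, with 251 changed at least 2-fold. The count was 170 without sorbitol 0 h A and 180 without sorbitol 6 h A. With NaCl 0 h as the control 771 probes changed, 214 of them called the same way against sorbitol 0 h. The count was 568 with both 0 h groups pooled, 149 with median scaling and 23 with the authors' deposited table, in which CL177Contig1_346_381 was not called. With the authors' normalization rebuilt it was 284.

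After 24 h in sorbitol, probe Bg04-21_I17_25_59 (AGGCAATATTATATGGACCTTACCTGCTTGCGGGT) rose from 8.96 ± 0.21 to 14.46 ± 0.55 (SD, n = 3), a log2 fold change of 5.51 (SE 0.29, limma adjusted p = 1.99e-10). Probe Bg04-30_K13_568_603 (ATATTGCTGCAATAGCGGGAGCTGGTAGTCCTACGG) was not above the negative controls at 0 h (7.77 ± 0.69) and reached 12.86 ± 0.99, at least 23.0-fold higher (limma adjusted p = 1.78e-07). CL192Contig1_771_805 (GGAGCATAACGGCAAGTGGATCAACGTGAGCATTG) fell from 14.02 ± 0.09 to 9.78 ± 1.46, a log2 fold change of -4.24 (SE 0.48, limma adjusted p = 3.73e-06). CL70Contig1_705_739 (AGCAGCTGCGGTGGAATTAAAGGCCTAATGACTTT) fell from 12.45 ± 0.24 to 9.58 ± 1.93, a log2 fold change of -2.87 (SE 0.57, limma adjusted p = 0.00220). In total 425 probes rose and 397 fell, 822 of 8655 (51.7% higher), and 672 changed at least 2-fold. The count was 457 without sorbitol 24 h C, 499 without sorbitol 24 h B, 479 without sorbitol 0 h A and 339 without the 4 arrays of lowest signal (63.7% higher). With NaCl 0 h as the control 2108 probes changed, 696 of them called the same way against sorbitol 0 h. The count was 1870 with both 0 h groups pooled, 470 with median scaling and 110 with the authors' deposited table (74.5% higher), in which CL70Contig1_705_739 was not called. With the authors' normalization rebuilt it was 866.

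**Figure D2:**
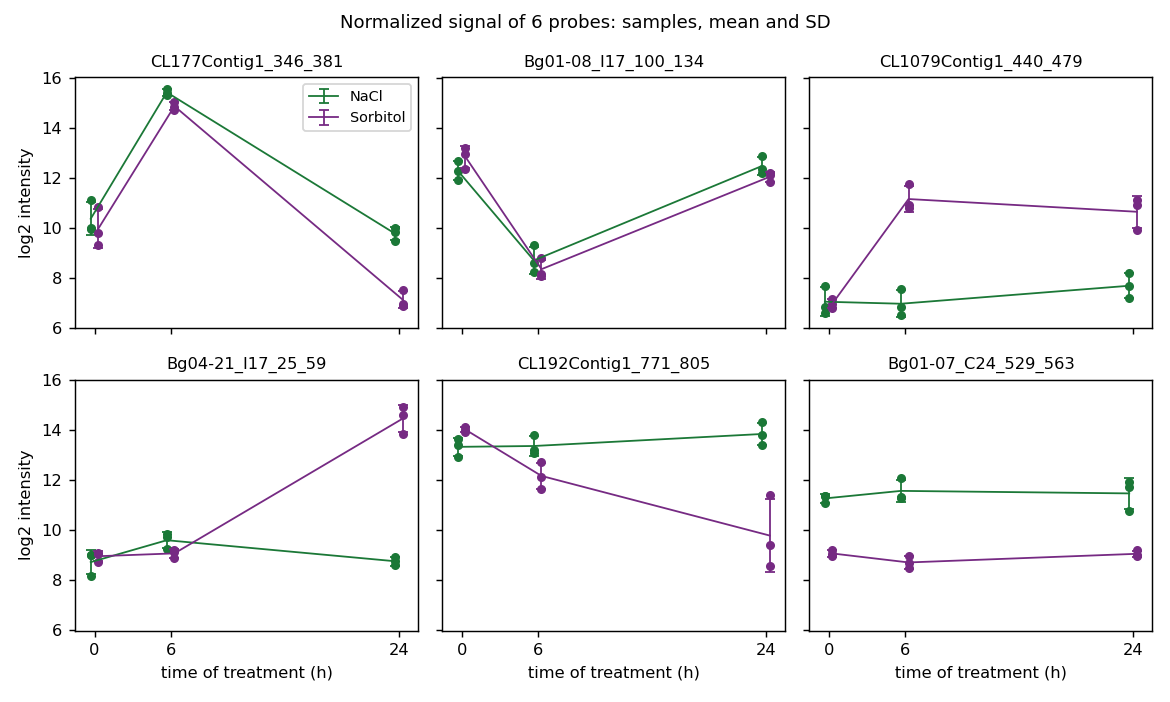
Normalized log2 intensity of 6 probes against hours of treatment, with points for the 3 samples of each group, lines through the group means and bars of 1 SD. CL177Contig1_346_381 stands at 15.42 (NaCl) and 14.86 (sorbitol) at 6 h and lies at 9.76 and 7.12 at 24 h, and Bg04-21_I17_25_59 reaches 14.46 in sorbitol at 24 h against 8.76 in NaCl.

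The difference between the responses to both treatments was tested directly, each against its own 0 h group. At 6 h the rise of Bg05-07_H14_769_803 in NaCl (11.12 ± 1.95 at 6 h, SD, n = 3) had no counterpart past the negative controls in sorbitol (6.66 ± 0.48). It stood at 7.88 ± 1.43 in sorbitol 0 h, above the negative controls in 1 of 3 samples. The fitted difference of responses was 5.72 (SE 0.99, limma adjusted p = 0.0128), which rests on undetected groups and is no exact size. The call was lost with median scaling, with the authors' normalization rebuilt and without NaCl 6 h B. Bg01-04_G02_513_547 (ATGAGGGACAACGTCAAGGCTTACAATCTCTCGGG) went from 9.66 ± 0.49 to 11.66 ± 0.57 in NaCl and from 10.95 ± 0.19 to 9.98 ± 0.22 in sorbitol, a difference of 2.96 (SE 0.46, limma adjusted p = 0.00527). CL1079Contig1_440_479 was not above the negative controls in NaCl at any time (6.96 ± 0.53 at 6 h), and its fitted difference, no exact size for that reason, was -4.26 (SE 0.53, limma adjusted p = 0.000763). Bg04-17_B15_512_550 (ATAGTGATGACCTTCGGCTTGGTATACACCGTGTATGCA) stood at 12.08 ± 0.19 in sorbitol and 8.72 ± 0.30 in NaCl at 6 h, a difference of responses of -3.29 (SE 0.51, limma adjusted p = 0.00527). In total 25 probes differed, 5 with a higher NaCl response and 20 with a lower one (20.0% higher), and 1610 had an unadjusted p under 0.05. The count ranged from 5 without NaCl 6 h B to 378 without NaCl 0 h C. It was 7 without NaCl 0 h B, 9 without NaCl 6 h A, 16 without NaCl 6 h C, and 14 without NaCl 24 h B. It was 8 without sorbitol 0 h A or B, 12 without sorbitol 0 h C, 51 without sorbitol 6 h A, 7 without sorbitol 6 h B and 10 without sorbitol 6 h C. It was 137 among probes detected in all 18 samples, 86 with a trended and robust eBayes, 87 with the 4 arrays of lowest signal as a block and 75 with the authors' normalization rebuilt (30.7% higher). It was 56 with only the first array of NaCl 0 h C, 9 without the filter on dim probes, 5 with median scaling and 0 with the authors' deposited table, where none of the 4 named probes was called.

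At 24 h, CL192Contig1_771_805 was lower after sorbitol (9.78 ± 1.46, SD, n = 3) and stood at 13.85 ± 0.44 in NaCl, a difference of responses of 4.75 (SE 0.67, limma adjusted p = 0.000460). CL70Contig1_705_739 stood at 12.33 ± 0.37 in NaCl and 9.58 ± 1.93 in sorbitol, a difference of 3.25 (SE 0.80, limma adjusted p = 0.0364). That call was lost in 13 of 29 other fits: normexp at offset 0, a trended and robust eBayes, no floor arrays, the authors' table, and without NaCl 0 h B or C, any NaCl 24 h sample, any sorbitol 0 h sample or sorbitol 24 h B. Bg04-21_I17_25_59 stood at 8.76 ± 0.17 in NaCl and 14.46 ± 0.55 in sorbitol, a difference of -5.47 (SE 0.42, limma adjusted p = 1.62e-07). Bg04-30_K13_568_603 was not above the negative controls in NaCl (6.24 ± 0.36) and reached 12.86 ± 0.99 in sorbitol, a fitted difference of -5.95 (SE 0.62, limma adjusted p = 1.55e-05) that is no exact size. In total 176 probes differed, 65 with a higher NaCl response and 111 with a lower one (36.9% higher). With median scaling 72 differed, 25.0% of them higher. The count was 72 without NaCl 0 h B, 105 without NaCl 24 h A, 87 without NaCl 24 h B, 98 without sorbitol 0 h A, 108 without sorbitol 0 h B, 268 without sorbitol 24 h A and 86 without sorbitol 24 h B. It was 93 without the 4 arrays of lowest signal and 106 among probes detected in all 18 samples (57 of them higher). With the authors' deposited table it was 0, so none of the 4 named probes was called there, and with the authors' normalization rebuilt it was 214. In the fit reported here 1525 probes had an unadjusted p under 0.05.

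Some probes were called in the same direction in both treatments. No untreated leaves of 6 h or 24 h were among the samples. A change common to both is therefore not separated from one that untreated leaves would also show. At 6 h, 71 probes rose and 54 fell in both, against 11.4 and 9.06 that independent lists of these sizes would share, and 1 probe fell in NaCl and rose in sorbitol. At 24 h, 67 probes rose in both, against 6.97 for independent lists, whereas 5 fell in both, against 9.04. Across the 8655 probes, which are not independent replicates, the log2 fold changes of NaCl and sorbitol correlated with r of 0.266 at 6 h (covariance 0.0870) and 0.253 at 24 h (covariance 0.0909). Both treatments have separate 0 h samples, and unchanged groups simulated in the same design gave r of 0.00669 and 0.00411 with covariances of 0.000734 and 0.000456. These simulations treat probes as independent; over samples the jackknife SE of r was 0.141 at 6 h and 0.128 at 24 h, so each r lay under 2 SE from 0. With the 0 h groups exchanged between the series, r at 24 h was 0.00879 and 34 probes were called in both in the same direction, in place of 72. At 6 h the exchange moved r by less than its jackknife SE and the number called in both by under 1.5 times. The exchange also brings in the NaCl minus sorbitol difference at 0 h, which correlated across probes with that at 24 h (r 0.253) but not with that at 6 h (r -0.00769). The number called in both was 80 without NaCl 0 h B and 81 without sorbitol 0 h A at 6 h, in place of 125. At 24 h it was 19 without NaCl 0 h B, 21 without NaCl 24 h B, 38 without NaCl 24 h C, 41 without NaCl 24 h A and 47 without sorbitol 0 h A. At 6 h and 24 h it was 50 and 12 with median scaling, 7 and 0 with the authors' deposited table and 74 and 47 without the 4 arrays of lowest signal. With both 0 h groups pooled it was 219 at 6 h (r 0.541), where both treatments share all controls, so that r is above 0 without any change. At 24 h it was 44 without the filter on dim probes and 110 with the authors' normalization rebuilt.

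**Figure D3:**
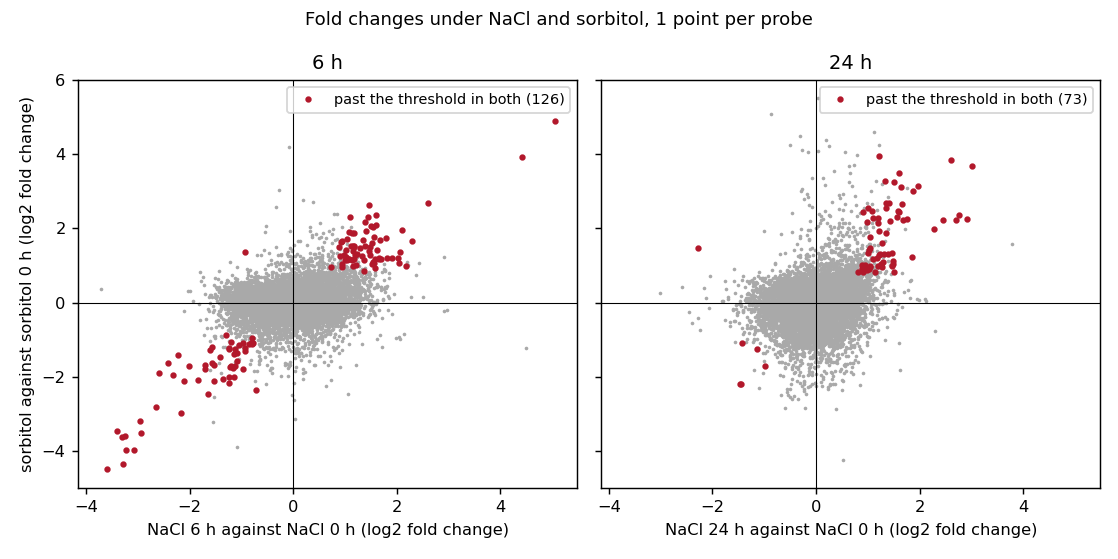
Log2 fold change against the own 0 h group in NaCl (horizontal) and sorbitol (vertical) for each tested probe at 6 h and 24 h, with probes past an adjusted p of 0.05 in both drawn in red. The red points at 6 h lie in the quadrants of common rise (71) and common fall (54), and those at 24 h in the quadrant of common rise (67) and, for 5 probes, of common fall, with 1 probe of opposite direction at each time.

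Between 6 h and 24 h in NaCl, CL177Contig1_346_381 fell from 15.42 ± 0.14 to 9.76 ± 0.26 (SD, n = 3), a log2 fold change of -5.66 (SE 0.35, limma adjusted p = 1.41e-09), a size that is not exact because 1 array at 6 h was saturated. Bg05-10_D05_200_234 (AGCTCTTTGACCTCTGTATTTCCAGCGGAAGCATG) fell from 15.58 ± 0.25 to 10.80 ± 0.21, a log2 fold change of -4.78 (SE 0.25, limma adjusted p = 9.16e-11), beside a 0 h level of 11.15 ± 0.25; this spot too was saturated on 1 array at 6 h. Bg05-21_D01_228_265 (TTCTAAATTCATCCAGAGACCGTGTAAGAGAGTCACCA) rose from 8.30 ± 0.75 to 12.20 ± 0.38, a log2 fold change of 3.89 (SE 0.59, limma adjusted p = 0.000330), and Bg01-08_E03_225_259 (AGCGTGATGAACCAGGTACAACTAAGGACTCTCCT) from 7.85 ± 0.49 to 11.68 ± 0.47, a log2 fold change of 3.83 (SE 0.37, limma adjusted p = 1.11e-06). In total 133 probes were higher and 86 lower at 24 h than at 6 h. Of the probes called at 6 h, 70 of 647 that had risen fell again and 76 of 659 that had fallen rose again, while 70 and 139 were still called in the same direction at 24 h. The counts of probes that turned back use the same 6 h samples in both comparisons. This favours apparent reversals, and no value for unchanged groups was taken for them. Fold changes at 6 h and 24 h share their 0 h samples: r across probes was 0.650 (covariance 0.225), against 0.501 (0.0554) for simulated unchanged groups, a difference of covariances of 0.170. Independent lists would share 10.6 and 15.0 calls, a reference that leaves out the shared 0 h samples. With sorbitol 0 h as the control for 24 h, so that no control was shared, r was 0.0667 (covariance 0.0196), so the likeness of 6 h and 24 h in NaCl was not separated from the shared controls. This control also brings in the NaCl minus sorbitol difference at 0 h. That difference had a covariance of -0.206 with the NaCl 6 h change, against -0.0547 for simulated unchanged groups. The low r therefore does not show that likeness is absent. The count of 219 was 133 without NaCl 6 h B, 117 without NaCl 24 h B, 115 with median scaling and 20 with the authors' deposited table, in which Bg05-21_D01_228_265 and CL177Contig1_346_381 were not called. With the authors' normalization rebuilt it was 243.

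Between 6 h and 24 h in sorbitol, CL177Contig1_346_381 went from 14.86 ± 0.16 to a level not above the negative controls (7.12 ± 0.35, SD, n = 3), at least 102-fold lower (limma adjusted p = 6.27e-12). Bg05-10_D05_200_234 fell from 14.90 ± 0.18 to 10.43 ± 0.34, a log2 fold change of -4.47 (SE 0.25, limma adjusted p = 1.14e-10). Bg04-21_I17_25_59 rose from 9.07 ± 0.17 to 14.46 ± 0.55, a log2 fold change of 5.39 (SE 0.29, limma adjusted p = 1.14e-10). CL15Contig1_574_608 (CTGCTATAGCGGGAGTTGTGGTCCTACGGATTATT) rose from 10.09 ± 0.97 to 14.08 ± 0.94, a log2 fold change of 3.99 (SE 0.53, limma adjusted p = 5.67e-05). In total 276 probes were higher and 191 lower at 24 h. Of the probes called at 6 h, 22 of 152 that had risen fell again and 56 of 119 that had fallen rose again, while 101 and 46 were still called in the same direction at 24 h, against 7.46 and 5.46 for independent lists. Both lists share their 0 h samples, so independent lists are not the value for no lasting change. The counts of probes that turned back likewise share their 6 h samples, which favours apparent reversals. Across probes r was 0.544 (covariance 0.185), against 0.5002 (0.0549) for simulated unchanged groups, a difference of covariances of 0.130. With NaCl 0 h as the control for 24 h, so that no control was shared, r was 0.335 (covariance 0.142). This control likewise brings in the difference between both 0 h groups. The count of 467 was 289 without sorbitol 6 h B, 279 without sorbitol 24 h C, 255 without the 4 arrays of lowest signal, 283 with median scaling and 52 with the authors' deposited table. With the authors' normalization rebuilt it was 454.

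Both untreated groups were compared as a measure of how the series differed before treatment. CL14Contig1_372_407 (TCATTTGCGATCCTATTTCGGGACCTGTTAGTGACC) stood at 9.44 ± 1.82 in NaCl 0 h and 14.58 ± 0.42 in sorbitol 0 h (SD, n = 3), a log2 difference of -5.14 (SE 0.81, limma adjusted p = 0.00245). Bg01-07_C24_529_563 (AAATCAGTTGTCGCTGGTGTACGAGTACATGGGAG) was higher in NaCl 0 h, 11.27 ± 0.17 against 9.07 ± 0.12, a log2 difference of 2.20 (SE 0.29, limma adjusted p = 0.000856). Bg02-01_J02_243_280 (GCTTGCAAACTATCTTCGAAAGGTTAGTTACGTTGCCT) was at least 3.40-fold higher in NaCl 0 h, 10.10 ± 0.35 against 7.41 ± 0.55, where it was not above the negative controls (limma adjusted p = 0.0117), a call lost without NaCl 0 h A, NaCl 0 h B or sorbitol 0 h A. In total 70 probes differed, 26 higher and 44 lower in NaCl 0 h (37.1% higher). With median scaling, which moved the median of all probes to -0.13, 43 differed, 9.30% of them higher. The count was 28 without NaCl 0 h A, 20 without NaCl 0 h B, 290 without NaCl 0 h C, 36 without sorbitol 0 h A, 24 without sorbitol 0 h B and 40 without sorbitol 0 h C. It was 117 among probes detected in all 18 samples, 45 with normexp at offset 0 and 1 with the authors' deposited table, in which CL14Contig1_372_407, Bg01-07_C24_529_563 and Bg02-01_J02_243_280 were not called. With the authors' normalization rebuilt it was 79. On the first principal component, 26.9% of the variance, NaCl 0 h A and B had the lowest scores of all samples (-44.4 and -36.5), NaCl 0 h C had -13.9, and the sorbitol 24 h samples had 32.9, 40.6 and 55.7. Groups were not cleanly separated on it: sorbitol 6 h A had 31.6, sorbitol 6 h B and C had 1.65 and 2.17, and NaCl 24 h B had -24.0.

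The repeat array of the NaCl 0 h C RNA gave the technical spread. The log2 difference between both arrays had an SD of 0.414 over 8655 probes (r = 0.963 across probes). For pairs of samples of the same group the SD was 0.459 to 0.762 (median 0.578, 18 pairs), so each pair of replicates differed by more than the repeated hybridisation did.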

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

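The tests chosen only after the result was seen are, for the difference between both 0 h groups, those of the floor arrays, of GC content, of a lasting difference (3 tests) and of the overlap of samples; the tests on the 6 h changes, on single 0 h samples and on other splits were chosen before.

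Responses to both treatments differed by a direct test in 25 probes at 6 h and 176 at 24 h (limma), and the response within a treatment changed between 6 h and 24 h in 219 probes for NaCl and 467 for sorbitol. The differences of responses (NaCl minus sorbitol, log2) at 6 h were 5.72 for Bg05-07_H14_769_803, 2.96 for Bg01-04_G02_513_547, -4.26 for CL1079Contig1_440_479 and -3.29 for Bg04-17_B15_512_550; the values of 5.72 and -4.26 rest on undetected groups and are no exact sizes. At 24 h they were 4.75 for CL192Contig1_771_805, 3.25 for CL70Contig1_705_739, -5.95 for Bg04-30_K13_568_603 (likewise no exact size) and -5.47 for Bg04-21_I17_25_59. From 6 h to 24 h in NaCl the log2 changes were 3.89 for Bg05-21_D01_228_265, 3.83 for Bg01-08_E03_225_259, -5.66 for CL177Contig1_346_381 and -4.78 for Bg05-10_D05_200_234, the last 2 with 1 saturated array at 6 h each. In sorbitol they were 5.39 for Bg04-21_I17_25_59, 3.99 for CL15Contig1_574_608, -7.74 for CL177Contig1_346_381 (a fitted value, the probe being below the detection threshold at 24 h) and -4.47 for Bg05-10_D05_200_234. Among spots outside the comparisons, the median of those named QC-3prime, QC-5prime and QC-LLD lay above the empty spots on 19 of 19 arrays each, and that of the negative controls on 16 of 19.

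The samples of each pair of groups were also split in other ways, all 10 of them or 100 drawn at random for the differences of responses, to see how many probes chance groupings of them give. With 3 samples against 3 there are 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave as many probes in each of these comparisons. The real count and the highest of the other splits were 1306 and 0 for NaCl 6 h, 339 and 1 for NaCl 24 h, 271 and 0 for sorbitol 6 h, 822 and 0 for sorbitol 24 h, 219 and 0 for NaCl 24 h against 6 h, 467 and 59 for sorbitol 24 h against 6 h, and 70 and 0 for both 0 h groups. The other splits mix both groups, so any difference between the groups enters the spread and lowers their counts. Their low counts therefore do not show how many probes chance alone would give. For the difference of responses at 6 h, 2 of 100 splits gave as many as the real 25 (highest other 28), a share under 0.05. This share does not exclude chance, because splits that mix NaCl and sorbitol samples of 6 h add any difference between them to the spread. The split of 28 likewise kept the 3 samples of each 6 h group together and mixed only 0 h samples, and the real count fell to 5 without NaCl 6 h B. For that at 24 h, 5 of 100 splits gave as many as the real 176 (highest other 976), so chance is not excluded. Each of those that reached 176 kept the 3 samples of each 24 h group together and regrouped at most the 0 h samples, so a structure of the samples, the NaCl and sorbitol groups at 24 h, stayed intact in them. A split that gave 655 probes exchanged both 0 h groups whole, so that each response was taken against the 0 h group of the other series.

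A pattern to follow up is that 70 probes differed between leaves not yet treated. Without the floor arrays 49 probes differed, which argues against these arrays as the cause. Over all tested probes the log2 difference correlated with GC content with r of only 0.0675. This argues against GC content for the difference across all probes, but the 70 called probes were not examined alone. Among the 70 probes the difference at 0 h correlated with those at 6 h and 24 h, measured in other samples, with r of 0.725 and 0.787, 44 of 70 kept its sign at both times and 24 were at least 2-fold apart the same way, whereas over all tested probes r was 0.253 with 24 h but -0.00769 with 6 h. A difference that lasts in part of these probes may therefore be present, while a difference across the whole set is not seen at 6 h. It cannot be told apart whether plants or arrays of each series carry it, since they go together in the design (that 69 of the 70 have samples that do not overlap is nearly fixed by how they were selected and decides nothing), and how far single samples set the count stays open (lowest count 20, without NaCl 0 h B).

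Another pattern is the 45 probes (14 up, 31 down) called in both treatments at 6 h that turned back by 24 h in both, CL177Contig1_346_381 and Bg05-10_D05_200_234 among those that rose and Bg01-08_I17_100_134 and Bg02-09_D21_98_132 among those that fell. Within a treatment the 6 h samples enter both calls, which favours apparent reversals. Turning back is not always a return to the 0 h level: in sorbitol CL177Contig1_346_381 stood at 9.97 at 0 h and 7.12 at 24 h. The departure of 6 h from the mean of 0 h and 24 h correlated between NaCl and sorbitol, which share no samples, with r of 0.217 across probes, above the highest of 100 simulations of unchanged, independent probes (0.0332), but its jackknife SE over samples was 0.185 and it fell to 0.0927 with 1 sample left out, so r alone does not separate it from 0. Without the floor arrays r was 0.259, so these arrays do not account for it. A response common to both stresses is a candidate explanation, and so is the time of day, since 6 h falls at another point of the day than 0 h and 24 h. These cannot be told apart for the 45 probes, because no untreated leaves of 6 h are among the samples.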

How the results depend on the processing

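The fit without the floor arrays, the floor arrays as a block, the other series' 0 h group as the control and the authors' normalization rebuilt were chosen after seeing the data; all other alternatives were chosen earlier. Arrays limit what can be seen near the negative controls, since dim probes have only bounds. Of 1086 values of named probes under the alternatives 1040 kept their call, 46 lost it (22 of them under the authors' deposited table) and 0 changed sign. CL70Contig1_705_739 lost the 24 h difference in 13, Bg05-22_G23_137_171 its NaCl 24 h call in 7 and Bg05-07_H14_769_803 the 6 h difference in 4. Bg02-01_J02_243_280 lost its call between both 0 h groups in 4. Without background correction each count stayed within 1.5 times (1289, 326, 268, 811, 23, 169, 226, 464 and 72, in the order NaCl 6 h, NaCl 24 h, sorbitol 6 h and sorbitol 24 h against 0 h, difference of responses at 6 h and 24 h, NaCl and sorbitol 24 h against 6 h, and both 0 h groups). Except where stated, the cause of a change was not tested.

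With median scaling the counts in that order were 308, 34, 149, 470, 5, 72, 115, 283 and 43, and 50 and 12 probes were called in both treatments at 6 h and 24 h. With the authors' deposited table, whose columns are on different scales, they were 8, 0, 23, 110, 0, 0, 20, 52 and 1. There 7 and 0 were called in both treatments, and the SD of the technical repeat was 0.539. Using only the first array of NaCl 0 h C there left NaCl 6 h at 8, so averaging in its repeat was not the reason. With the authors' normalization rebuilt for all samples the counts in that order were 1474, 386, 284, 866, 75, 214, 243, 454 and 79. These values argue against that normalization as the reason for the low counts. The low counts went with the columns left as scanned, sorbitol 24 h B and C, whose spread enters the common model of every comparison. With normexp at offset 0 both 0 h groups differed in 45 probes and the technical SD was 0.556.

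Without the filter on dim probes NaCl 24 h gave 184, the difference at 6 h 9 and probes called in both at 24 h 44. Among probes detected in all 18 samples the differences of responses gave 137 at 6 h and 106 at 24 h and both 0 h groups 117. A trended and robust eBayes gave 86 for the difference at 6 h, and only the first array of NaCl 0 h C gave 56. With both 0 h groups pooled the 4 treatment counts were 683, 121, 568 and 1870, with 219 in both at 6 h and r of 0.541; pooling makes the controls shared between both treatments. With the other series' 0 h group they were 217, 85, 771 and 2108, with 34 in both at 24 h and r of 0.00879. At 6 h the number in both moved by under 1.5 times and r by less than its jackknife SE.

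Without the floor arrays, with fewer samples, NaCl 6 h gave 844, sorbitol 24 h 339, the 24 h difference 93 and sorbitol 24 h against 6 h 255, with 74 and 47 called in both at 6 h and 24 h. The floor arrays as a block gave 87 for the 6 h difference. The authors' normalization rebuilt gave 75 there and 110 in both at 24 h.

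The letters A, B and C were not taken as pairs, since 26, not all, of 45 pairs of same-letter samples had correlated deviations over 0.1 (range -0.302 to 0.477). In 2 of 15 pairs of groups all 3 letters did, sorbitol 0 h with 6 h (0.477, 0.208 and 0.370) and NaCl 0 h with sorbitol 24 h. Of the 45, 23 correlated best with their own letter, where chance gives 15, a hint from the data that letters may share something. With the letter as a replicate block NaCl 24 h gave 623, the differences of responses 270 at 6 h and 319 at 24 h, both 0 h groups 116 and probes called in both at 24 h 146. The block moved no other count by over 1.5 times (sorbitol 6 h 337 in place of 271).

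Leaving out 1 sample at a time gave 331 to 2029 for NaCl 6 h, 36 to 555 for NaCl 24 h, 170 to 301 for sorbitol 6 h and 457 to 916 for sorbitol 24 h. It gave 5 to 378 for the 6 h difference, 72 to 268 for the 24 h difference, 117 to 255 for NaCl 24 h against 6 h, 279 to 558 for sorbitol 24 h against 6 h and 20 to 290 for both 0 h groups. Probes called in both ranged from 80 to 135 at 6 h and from 19 to 101 at 24 h. The files give no slide or scan date and no genes for probes, so a block on the date, 1 probe per gene and camera on gene lists were not run.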

Other observations

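The tests on contig probes and on clone prefixes were chosen only after their result was seen.

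Some probes repeat each other's measurement. Bg01-08_I17_100_134 and Bg02-09_D21_98_132 share 33 consecutive bases, and at NaCl 6 h they stood at 8.69 ± 0.55 and 9.05 ± 0.29 (SD, n = 3) after 12.28 ± 0.37 and 12.33 ± 0.43 at 0 h. Among 52 pairs of kept probes with the same sequence, the log2 fold changes correlated across pairs with r of 0.815 at NaCl 6 h and 0.858 at sorbitol 24 h. The log2 difference within a pair had an SD of 0.591 over all pairs and samples together, which includes any constant offset between the probes of a pair. Probes called in the same direction at 6 h and 24 h in both treatments numbered 12 up and 1 down.

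Contig probes as a group lay higher than single-clone probes in NaCl against NaCl 0 h: the medians of log2 fold change differed by 0.26 at 6 h and 0.23 at 24 h, and by 0.03 at sorbitol 6 h. With the preset correlation camera gave an adjusted p of 0.000578 at NaCl 6 h, which became an adjusted p of 0.350 with an estimated correlation. With sorbitol 0 h as the control the difference at NaCl 6 h was 0.0792, so the shift goes with the NaCl 0 h samples and may be a property of them. Clone probes matched on signal level lay -0.0177 from all clone probes, which argues against signal level as the cause. No biological explanation was tested, since the files do not say what distinguishes contigs from single clones beyond their names.

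Over 6 sets of probes (contigs and 5 clone prefixes) in the 4 treatment comparisons, the lowest adjusted p of camera with an estimated correlation was 0.112.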
